A study of Homo sapiens with 39 samples.

How the data were processed

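Polymorphonuclear leukocytes (PMN, the blood fraction that is mainly neutrophils) were obtained from healthy individuals, and total RNA was labelled with biotin and hybridised to 1-colour oligonucleotide arrays, per the labels. The 39 arrays comprised 9 time-zero controls, 3 arrays of untreated cells at each of 3, 6, 12, 18 and 24 h, and 3 arrays of cells cultured with 100 ng/ml GM-CSF at each of the same 5 times. Group, time and replicate number were read from the sample titles. The labels do not say whether replicates came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical. The highest share of identical values between any 2 arrays was 0.943%, and no array was counted as a duplicate of another.

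The deposited value table held, for each of 12625 probe sets on each array, a ratio: per the values themselves, the signal of the probe set over a constant of its own that was shared by all 39 arrays. How the authors computed the signal, the constant and any scaling between arrays is not given in the sources used here. The ratios ran from 0.01 to 94.4 with a median of 0.955, and 54 values lay at the floor of 0.01. Levels of different probe sets can therefore not be set against each other. For dim probe sets the constant could be recovered, because a signal rounded to a fixed step and divided by a constant leaves ratios that are whole multiples of 1 step. A constant of up to 600 rounding steps was found for 7294 probe sets (57.8%). The same search found 0 constants in 1000 probe sets whose values had been moved off the grid, and on simulated probe sets it returned the true constant for 148 of 154 within its range and none for 146 of 146 beyond it. Probe sets without a recovered constant are called bright. Scanner values, background and detection calls were not used here, so the number of arrays is the stated limit on precision.

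The tests planned before the data were examined assumed intensities, with an offset on the log scale, quantile normalization and 1 probe set per gene chosen by brightness. Ratios needed another setting, and the planned one was kept as an alternative. The log2 of the ratio was taken with no offset. A probe set was kept where its recovered signal lay above the median signal (491.9 rounding steps), or was bright, in at least 3 arrays, which kept 8916, and 67 control probe sets were left out. The 2% trimmed means of the arrays differed by 2.67-fold, beyond the limit of 1.1-fold fixed beforehand, so the arrays were rescaled. The plan named quantile normalization for this case. Instead, each array was centred on the median of its kept probe sets, a choice made once the values were known to be ratios. Quantile normalization was run as an alternative. Of all probe sets, 10943 carried 1 gene symbol, 545 several and 1070 none, and the gene identifiers of 10934 were found in the current gene table, from which symbols were updated. No gene was named from a probe set with several symbols. The mean of the kept probe sets of a gene was used, which gave 6275 genes, 1159 of them with more than 1 probe set. Gene-specific differences between probe sets are stated where they affect a named gene.

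Each gene was fitted with limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) over all 39 arrays with 11 groups and 28 residual degrees of freedom, and was called at a Benjamini-Hochberg adjusted p under 0.05 in that comparison. The comparisons were GM-CSF minus untreated at each time and averaged over the 5 times, the moderated F test of whether that difference changed with time, and untreated and GM-CSF-treated cells at each time against time zero. All values named as differences are on the log2 scale, with standard errors from the fit. All p-values of single genes are limma's, adjusted over the 6275 genes, unless stated otherwise.

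A total of 35 gene lists (pathways, complexes and cell-type markers) was fixed before the data were examined. Each list had at least 5 measured genes and was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, with the estimated correlation (and statmod 1.5.0 for block correlations) and fry as alternatives. Beside each list stands the number of its genes called over all genes tested, and, where it differs, the number adjusted over the list alone. The genes named in the text follow a rule fixed at the same time: the 12 largest rises and falls of the mean GM-CSF effect with 1 sign at all 5 times, the 3 largest rises and falls at each time, the 8 largest interaction F values, the 10 largest rises and falls in untreated cells at 24 h and 3 at each earlier time, the 5 largest rises and falls with GM-CSF at 24 h, up to 4 genes of the smallest p per list, and a fixed set of receptor, survival and inflammatory genes. Immunoglobulin and T cell receptor segments, HLA-DRB and HLA-DQ genes, GSTM1, and genes of the sex chromosomes that mark sex were left out. CISH, in the fixed set, was not measured after the filter.

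The fit was tested on simulated data for 6275 genes. For GM-CSF minus untreated at 24 h it recovered 2%, 24%, 64% and 88% of 50 genes each changed by 0.5, 1, 2 and 3 log2 units, and called 6 of 6075 unchanged genes. For untreated 24 h minus 0 h it recovered 6%, 34%, 76% and 94%, again with 6 of 6075 unchanged genes called. In both comparisons 3 of 3 gene lists raised by 1 log2 unit were recovered. The simulated genes were drawn independently of each other and most were unchanged. The simulation therefore does not test the lists under correlation between genes, or the fit where most genes change.

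Alternatives to scaling, offset, filter, probe-set choice, variance model, arrays in the fit, replicate block, fold limit and left-out arrays were computed for the results to which each applies. The similarity of the changes with and without GM-CSF was measured across genes with the 9 time-zero arrays split between both comparisons. The changes shared through those arrays were simulated with unchanged groups. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.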

Results

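Transcript levels were measured in human polymorphonuclear leukocytes kept in culture with or without GM-CSF, a cytokine that activates neutrophils and prolongs their survival. The 39 arrays covered 9 time-zero samples, and 3 samples without and 3 with GM-CSF (100 ng/ml) at each of 3, 6, 12, 18 and 24 h. The design addresses how neutrophil transcripts change over a day of culture, how GM-CSF alters that course, and whether its effect depends on time. A total of 6275 genes passed the filter. The array medians of the deposited ratios ranged from 0.74 to 1.92. On the deposited scale the median kept probe set lay at a log2 ratio of -0.14 ± 0.10 (SD, n = 9) at time zero. It lay at -0.04, 0.02, 0.18, 0.28 and 0.46 in untreated cells from 3 to 24 h, and at -0.26, -0.31, -0.26, -0.10 and 0.03 with GM-CSF (n = 3 each). All differences reported are relative to the array median, and where centring moved the balance of higher and lower calls both splits are given.

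Control probe sets showed that some groups of arrays stood apart. The bacterial spike-ins BioB, BioC and BioDn, which are added with the hybridisation mixture, lay at a deposited log2 ratio of -0.88 ± 0.61 (SD, n = 9) at time zero, and higher late in culture. In untreated cells they lay at 0.80 ± 0.75 at 18 h and 1.39 ± 0.56 at 24 h, and with GM-CSF at 0.75 ± 0.31 at 24 h (n = 3 each). The actin 3′ minus 5′ difference, a measure of RNA integrity, was -0.64 ± 0.44 at time zero and 0.78 ± 0.38 in untreated cells at 24 h. In untreated cells at 3 and 6 h it was -1.74 ± 0.59 and -2.47 ± 1.62. On the 6 untreated arrays of 3 and 6 h, 13 bright probe sets lay below 0.25 of their lowest ratio on the other 33 arrays, where no other pair of groups had any. They included the probe sets of OAZ1, FTL and TMSB4X and 1 of the probe sets of each of B2M, GAPDH and CXCL8. IFITM3 and TAGLN2 were also low on these arrays. One B2M probe set had a mean ratio of 0.01 on these 6 arrays and another of 0.28. For genes affected in this way the mean of the 12, 18 and 24 h differences is given beside the mean over all times.

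**Figure D1:**
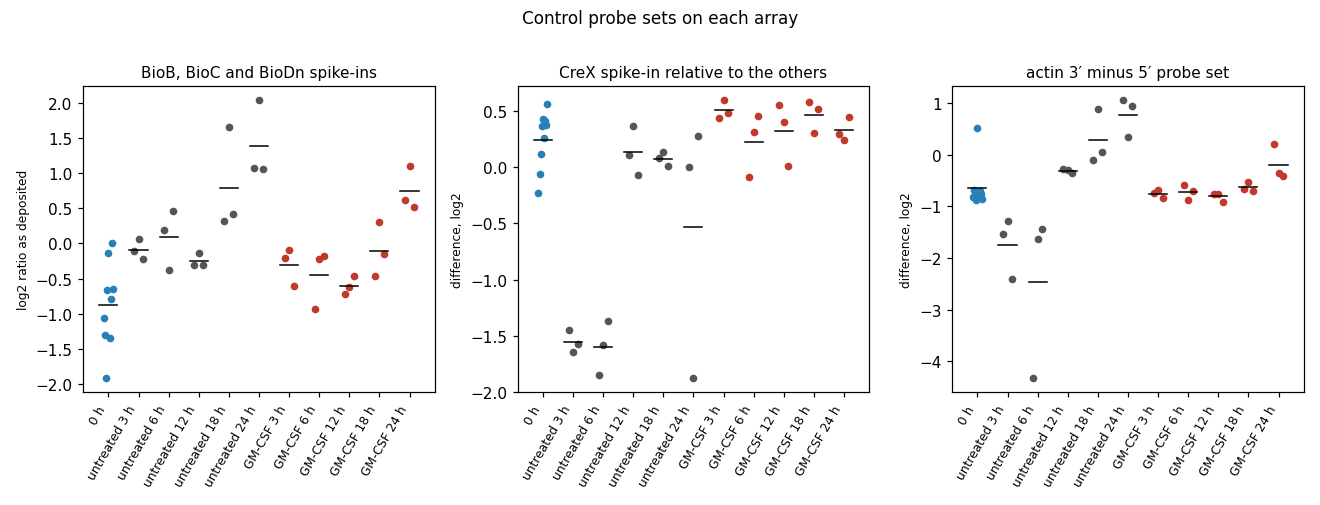
Deposited log2 ratios of the bacterial spike-ins, of the CreX spike-in relative to the others, and of the actin 3′ minus 5′ difference on each of the 39 arrays, by group; points are arrays and bars are group means. The spike-ins were highest in untreated cells at 24 h (mean 1.39), and CreX, measured by its 3′ probe set, lay low on the 6 untreated 3 h and 6 h arrays (mean -1.58, against 0.21 on the other 33). Of these 33, untreated 24 h replicate 2 lay at -1.88.

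In cells cultured for 24 h without GM-CSF, the largest fall from time zero was in FCN1, a secreted lectin of innate immunity (-7.40 ± 0.30, SE, adjusted p = 1.9e-18, 3 arrays against 9). ITGAM, the integrin CD11b (-7.09 ± 0.52), and MXD1, an antagonist of MYC (-6.28 ± 0.44), came next. They were followed by SERPINB1, an inhibitor of neutrophil proteases (-6.11 ± 0.46), G0S2, an inhibitor of lipolysis (-5.90 ± 0.72), and VIM, an intermediate filament protein (-5.69 ± 0.36). Below them were the retinoic acid receptor RARA (-5.55 ± 0.32), NACC2 (-5.49 ± 0.56), the motor protein MYO5A (-5.44 ± 0.40) and FRAT2 (-5.17 ± 0.59). Among the genes chosen in advance, CSF2RA, the GM-CSF receptor alpha chain, fell by 4.45 on the log2 scale. BCL2A1, an anti-apoptotic BCL2 relative, fell by 3.57, FCGR3B, the IgG receptor CD16b, by 3.44, and MCL1, a survival factor of neutrophils, by 2.52. The 10 largest rises all came from dim probe sets, namely CLGN (4.66 ± 0.67), FRK (4.39 ± 0.52), HSPA4L (4.10 ± 0.86), TAC1 (4.04 ± 0.75) and PPM1E (3.99 ± 0.52). PCK1 (3.92 ± 0.58), PRKG1 (3.91 ± 0.73), GRIA2 (3.84 ± 0.70), ADIPOQ (3.78 ± 0.61) and RAG1 (3.77 ± 0.65) completed them. Of the 2344 genes called higher at 24 h, 1330 (56.7%) had only dim probe sets, against 12.2% of those called lower, on the arrays where the spike-ins were highest. The filter could keep a dim probe set through high signals on these 3 arrays alone, so part of this contrast may come from the filter. In the setting first planned MYO5A lay at 0.32. With the most precise probe set CXCR2, an interleukin-8 receptor that fell by 1.88, lay at 1.57.

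In untreated cells at 24 h 4624 of 6275 genes differed from time zero, 2344 higher and 2280 lower (3114 and 1648 as deposited). The numbers at 3, 6, 12 and 18 h were 1439, 1166, 1649 and 2652. These split into 634 higher and 805 lower (732 and 685 as deposited), 510 and 656 (695 and 526), 725 and 924 (1563 and 562), and 1204 and 1448 (2338 and 838). They fell to 946 without untreated 3 h replicate 1, 736 without untreated 6 h replicate 1, 396 without untreated 12 h replicate 2 and 726 without untreated 18 h replicate 2. Changes early in culture included rises of ZNF165 (7.18 ± 0.74 at 3 h and 6.71 ± 0.74 at 6 h), of OLR1, a receptor for oxidised lipoproteins (6.72 ± 0.41 and 5.42 ± 0.41), of the phosphatase DUSP2 (5.03 ± 0.66 at 3 h) and of CYP1B1 (4.85 ± 0.61 at 6 h). These early rises were measured on the 6 arrays that stood apart, and that of ZNF165 came from dim probe sets. At 12 h CCRL2, an atypical chemerin receptor (3.36 ± 0.42), and BMP6 (3.21 ± 0.48) were higher, and ALPL, the neutrophil alkaline phosphatase, was lower (-4.98 ± 0.42). ALPL remained low at 18 h (-5.41 ± 0.42), together with ITGAM (-5.67 ± 0.52) and FCN1 (-5.31 ± 0.30). OAZ1 (-6.59 ± 0.30 at 3 h), IFITM3 (-6.01 ± 0.56), TAGLN2 (-5.97 ± 0.44) and TMSB4X (-5.94 ± 0.29 at 6 h) had the largest early falls, all on the 6 arrays that stood apart.

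By gene list, 13 of 35 were called in untreated cells at 24 h and all 13 were lower, but 34 of 100 splits of the same arrays called as many. They were led by actin cytoskeleton and motility (0 genes higher and 32 lower of 35, adjusted p = 3.67e-07) and neutrophil markers (0 and 15 of 15, adjusted p = 4.48e-06). Next came oxidative phosphorylation (2 and 31 of 45, adjusted p = 3.57e-05), Fc and complement receptors and adhesion molecules (0 and 18 of 24, adjusted p = 6.92e-05) and GM-CSF receptor and JAK-STAT signalling (2 and 18 of 25, or 19 lower adjusted over the list alone, adjusted p = 0.00025). Lysosome and autophagy (2 and 25 of 34, adjusted p = 0.00042), NADPH oxidase (0 and 8 of 10, adjusted p = 0.00139), pattern recognition receptors (0 and 10 of 11, adjusted p = 0.00156) and proteasome subunits (3 and 20 of 33, adjusted p = 0.00204) were lower as well. MHC class I and antigen processing (1 and 12 of 15, or 13 lower adjusted over the list alone, adjusted p = 0.00915), chaperones (7 and 19 of 31, adjusted p = 0.0113), NF-kB genes (2 and 12 of 20, adjusted p = 0.026, and 0.254 after quantile normalization) and interferon-induced genes (1 and 16 of 29, adjusted p = 0.0271) completed them. With an estimated correlation none of the 13 was called. The adjusted p was 0.426 for 9 of them, 0.461 for the proteasome, 0.47 for MHC class I and NF-kB, and 0.687 for interferon-induced genes. Examples were VASP (-4.45 ± 0.49) and PFN1 (-2.44 ± 0.28) of the actin list and MGAM (-4.53 ± 0.46) and FPR1, the formyl peptide receptor (-3.68 ± 0.38), of the neutrophil markers. TLR2 (-3.53 ± 0.28) and TLR1 (-3.35 ± 0.33) fell among the pattern recognition receptors, and NDUFB3 (-3.34 ± 0.33) and SDHD (-2.77 ± 0.34) in oxidative phosphorylation. Further examples were GLA, a lysosomal galactosidase (-3.62 ± 0.35), VAV1 (-2.81 ± 0.36) of the NADPH oxidase list and PSMD11 (-3.45 ± 0.28) of the proteasome. The chaperones HSP90AA1 (-2.89 ± 0.24) and HSPA5 (-2.71 ± 0.27), PSMB8 (-2.79 ± 0.45) of the MHC class I list, TNIP1 (-4.00 ± 0.48) of the NF-kB list and the interferon-induced IFITM2 (-2.73 ± 0.31) fell too.

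The other lists were not called in untreated cells at 24 h. Cytosolic ribosomal proteins had 0 genes higher and 22 lower of 42 (20 lower adjusted over the list alone, adjusted p = 0.0723), antioxidant and NRF2 target genes 4 and 13 of 22 (adjusted p = 0.0723) and translation factors 4 and 14 of 34 (adjusted p = 0.0913). Caspases had 1 and 5 of 7 (adjusted p = 0.0976), glycolysis 4 and 16 of 29 (adjusted p = 0.0999), and chemoattractant receptors 1 and 10 of 17 (adjusted p = 0.113). Immediate-early genes had 6 and 9 of 25 (adjusted p = 0.192), BCL2 family and survival genes 5 and 7 of 14 (adjusted p = 0.233), death receptors 7 and 11 of 19 (adjusted p = 0.255) and p53 targets 4 and 6 of 14 (adjusted p = 0.551). Members of these lists that fell included RPL30 (-1.50 ± 0.26), NFE2L2, the regulator of antioxidant genes (-4.61 ± 0.45), EIF1 (-3.41 ± 0.35), CASP1 (-4.99 ± 0.53), ADM (-3.40 ± 0.26), DUSP1 (-4.91 ± 0.32) and FOS (-4.71 ± 0.43). Chemokines and inflammatory cytokines had 13 genes higher and 7 lower of 28 (adjusted p = 0.233), with CXCL5 higher (1.85 ± 0.26) and IL1RN, the interleukin-1 receptor antagonist, lower (-3.71 ± 0.30). Cell cycle genes had 16 higher and 6 lower of 27 (adjusted p = 0.0999). Median and mean had opposite signs for granule proteins (6 and 8 of 22, median 0.58, mean -0.17, adjusted p = 0.915) and cholesterol synthesis (5 and 4 of 15, 3 lower adjusted over the list alone, median 0.14, mean -0.01, adjusted p = 0.653). MHC class II (3 and 3 of 15, 2 lower adjusted over the list alone, adjusted p = 0.915) had a median of -0.13 and a test upward, with a median of 0.47 on the deposited scale. Eosinophil markers (2 and 1 of 6, adjusted p = 0.915) had a median of -0.14 and a test upward. Pro-apoptotic BCL2 relatives (3 and 4 of 12) had adjusted p = 0.928. Markers of T and NK cells (5 higher and 0 lower of 19, 4 higher adjusted over the list alone, adjusted p = 0.233) and B cells (4 and 0 of 6, adjusted p = 0.113) were not called, and neither were those of platelets (4 and 0 of 8, adjusted p = 0.551), erythroid cells (4 and 0 of 5, adjusted p = 0.0831) or monocytes (1 and 4 of 10, 3 lower adjusted over the list alone, adjusted p = 0.784).

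The rule for the mean GM-CSF effect named only called genes with the same sign at all 5 times. Among these, relative to untreated cells of the same time and averaged over the 5 times, the largest rises with GM-CSF were in SGK1, a kinase of cell survival (4.85 ± 0.19, SE, adjusted p = 2.8e-19, 15 arrays against 15) and the circadian regulator PER2 (4.82 ± 0.31). IL1RN (4.77 ± 0.17), RHOH, a haematopoietic GTPase (4.69 ± 0.28), ANXA3, an annexin of neutrophil granules (4.38 ± 0.27), and CD69, an early activation marker (4.35 ± 0.28), came next. SOCS1, a feedback inhibitor of cytokine signalling (4.03 ± 0.36), the transcription factor ETS2 (4.02 ± 0.19) and the mitochondrial protease PITRM1 (3.91 ± 0.17) were higher too. NDUFV2, a subunit of respiratory complex I (3.80 ± 0.15), the neutrophil chemokine CXCL8 (3.79 ± 0.20) and the nuclear receptor PPARG (3.75 ± 0.44) followed. The largest falls were in APOBEC3B, a cytidine deaminase (-3.75 ± 0.64), ZNF165 (-3.40 ± 0.41), and PTGES, a prostaglandin E synthase (-3.17 ± 0.26). PEG3 (-3.16 ± 0.40), GPR162 (-3.12 ± 0.53), CLGN (-2.85 ± 0.37) and HSPA4L (-2.84 ± 0.47) were next. SULT1C2 (-2.68 ± 0.39), ERBB4 (-2.66 ± 0.35), GRIA2 (-2.65 ± 0.38), FRK (-2.61 ± 0.28) and PPP1R12B (-2.56 ± 0.14) completed them. The same sign at each of the 5 times was the condition for naming these 24 genes and is not a result. Of them, 4 of the rises (PER2, SOCS1, PITRM1 and PPARG) and all the falls but those of APOBEC3B and PPP1R12B came from dim probe sets. CLGN, HSPA4L, GRIA2 and FRK were also among the largest rises in untreated cells at 24 h, where the spike-ins lay at 1.39, against 0.75 with GM-CSF. CXCL8 had a fallen probe set on the untreated 3 h and 6 h arrays, and its mean over 12, 18 and 24 h was 2.70 ± 0.26, against 5.87 ± 0.21 for IL1RN and 4.62 ± 0.25 for SGK1.

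**Figure D2:**
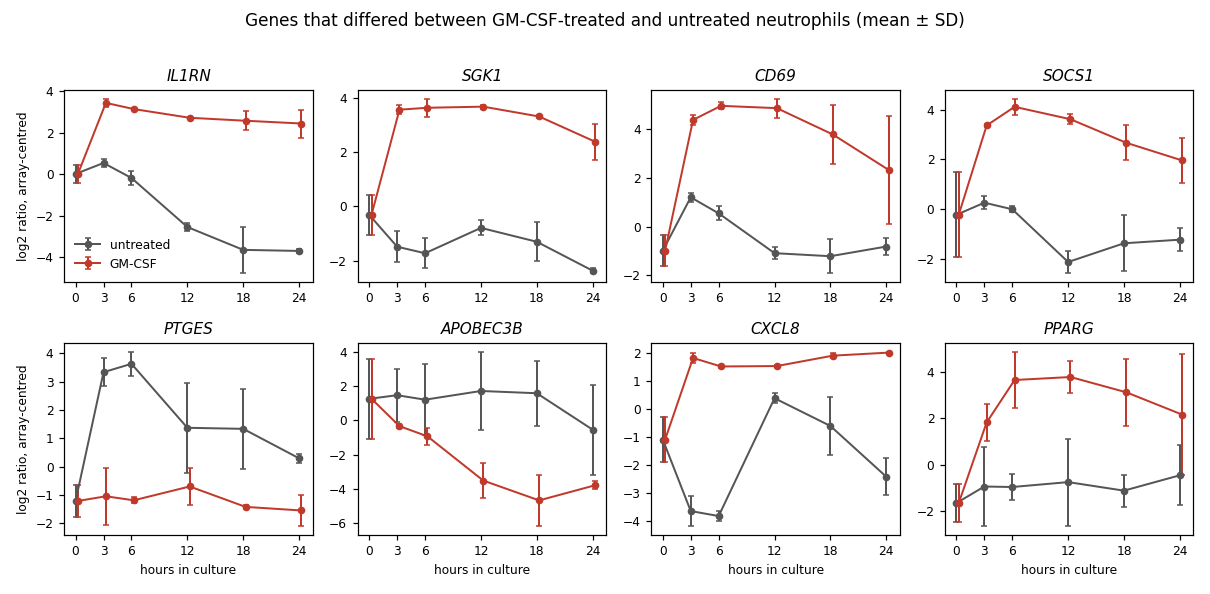
Centred log2 ratios of 8 genes against hours in culture, as mean ± SD for untreated cells (grey) and GM-CSF (red), with the 9 time-zero arrays as the shared first point and n = 3 at each later point. IL1RN, SGK1, CD69, SOCS1 and PPARG lay higher with GM-CSF at each of the 5 times, while PTGES and APOBEC3B lay lower, as the rule that chose them required. CXCL8 in untreated cells fell at 3 and 6 h, on the arrays with fallen probe sets.

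Averaged over the 5 times 4438 of 6275 genes differed, 2082 higher and 2356 lower (1487 and 3308 as deposited), and 1949 of them by at least 2-fold. At 3, 6, 12, 18 and 24 h the numbers were 1415, 1492, 2589, 2615 and 3850. Their splits were 731 higher and 684 lower (547 and 1035 as deposited), 834 and 658 (573 and 1220), 1355 and 1234 (884 and 2104), 1399 and 1216 (964 and 2013) and 2030 and 1820 (1571 and 2429). The 12 h number was 1630 without untreated 12 h replicate 2, and the 18 h number was 1536 without untreated 18 h replicate 2 and 1193 in a fit of the compared arrays alone. At 3 h the largest rises were in OAZ1 (7.04 ± 0.36), IFITM3 (6.60 ± 0.68) and TMSB4X (6.48 ± 0.36), which were low on the untreated arrays of that time. OAZ1 and TMSB4X had mean ratios of 0.012 and 0.014 there, next to the floor of 0.01, so the sizes and ranks of their early differences are not measured folds but depend on the floor. Their means over 12, 18 and 24 h were 0.33 ± 0.21, -0.48 ± 0.39 and 0.45 ± 0.21, and none was called. HMOX1, heme oxygenase 1, was lower with GM-CSF at 3 h (-5.24 ± 0.89), as were ADARB1 (-5.46 ± 0.59) and NRGN (-5.02 ± 0.90). At 6 h OAZ1, PER2 (6.65 ± 0.69) and IFITM3 were highest, while ZNF165 (-6.76 ± 0.91), NRGN (-5.07 ± 0.90) and PTGES (-4.82 ± 0.59) were lowest. At 12 h CD69 (5.97 ± 0.63), LHFPL2 (5.78 ± 0.85) and SOCS1 (5.73 ± 0.80) were highest and APOBEC3B (-5.25 ± 1.42), GPR162 (-4.98 ± 1.17) and ZNF165 (-4.22 ± 0.91) lowest. At 18 h IL1RN (6.22 ± 0.37), FCAR, the IgA receptor (6.13 ± 0.77), and ITGAM (5.43 ± 0.64) led. APOBEC3B (-6.27 ± 1.42), CLGN (-4.82 ± 0.82) and FRK (-4.38 ± 0.64) were at the other end. At 24 h ITGAM (6.73 ± 0.64), HMOX1 (6.46 ± 0.89) and FCAR (6.32 ± 0.77) were highest and CLGN (-5.68 ± 0.82), RARS2 (-4.98 ± 0.87) and GRIA2 (-4.61 ± 0.86) lowest. The calls of APOBEC3B at 12 and 18 h were lost with an offset of 1 on the log scale.

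Over the 5 times of GM-CSF against untreated cells, 21 of 35 lists were called, 19 higher and 2 lower, where other splits of the same arrays called a median of 10. Over 12, 18 and 24 h alone 19 were called, 18 higher and 1 lower, of which 0 held with an estimated correlation. Of 25 measured genes of the GM-CSF receptor and JAK-STAT list 17 were higher and 3 lower (adjusted p = 0.00077). Among them were IL3RA, the interleukin-3 receptor alpha chain (3.24 ± 0.22), CSF2RA (2.99 ± 0.21), CSF2RB, the common beta chain (2.29 ± 0.17), and the kinase PIM1 (2.07 ± 0.15). SOCS3 was higher by 3.25 ± 0.32. Fc and complement receptors and adhesion molecules had 17 higher and 2 lower of 24 (adjusted p = 1.05e-05), with CD44 (2.69 ± 0.13), CD63 (2.04 ± 0.14), FCGR2B (2.46 ± 0.17) and ITGAM (3.51 ± 0.28, and 5.72 ± 0.37 over 12 to 24 h). Pattern recognition receptors had 8 higher and 0 lower of 11 (adjusted p = 0.00239), with TLR2 (3.26 ± 0.15), TLR1 (2.46 ± 0.18), LY96 (2.64 ± 0.24) and CD14 (3.48 ± 0.33). Of 17 chemoattractant receptors 13 were higher and 2 lower (adjusted p = 0.0122). PTAFR, the platelet-activating factor receptor (2.81 ± 0.19), CCR1 (2.75 ± 0.19), PTGER4 (1.61 ± 0.18) and FPR2 (1.54 ± 0.18) were higher, whereas CXCR1, an interleukin-8 receptor, was lower (-1.14 ± 0.15). CXCR4, a receptor of bone marrow retention, was higher by 1.16 ± 0.14. Genes of the NADPH oxidase, the source of superoxide, had 7 higher and 0 lower of 10 (adjusted p = 0.00327), with RAP1B (2.73 ± 0.18), PRKCD (1.43 ± 0.15), RAC2 (1.96 ± 0.22) and CYBA (1.24 ± 0.16). CYBB, its catalytic subunit, was higher by 2.01 ± 0.34. NF-kB family and feedback genes had 14 higher and 1 lower of 20 (adjusted p = 0.00189), with IER3 (2.75 ± 0.19), NFKBIA (2.12 ± 0.17) and ICAM1 (1.60 ± 0.16). Chemokines and inflammatory cytokines had 14 higher and 8 lower of 28 (adjusted p = 0.0434), with CCL2 (3.09 ± 0.18), TNF (1.74 ± 0.14) and IL1B (2.07 ± 0.22) among those higher. With an estimated correlation none of the 21 calls held. For these lists the adjusted p was then 0.218, except 0.341 for the NADPH oxidase and 0.317 for NF-kB genes.

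**Figure D3:**
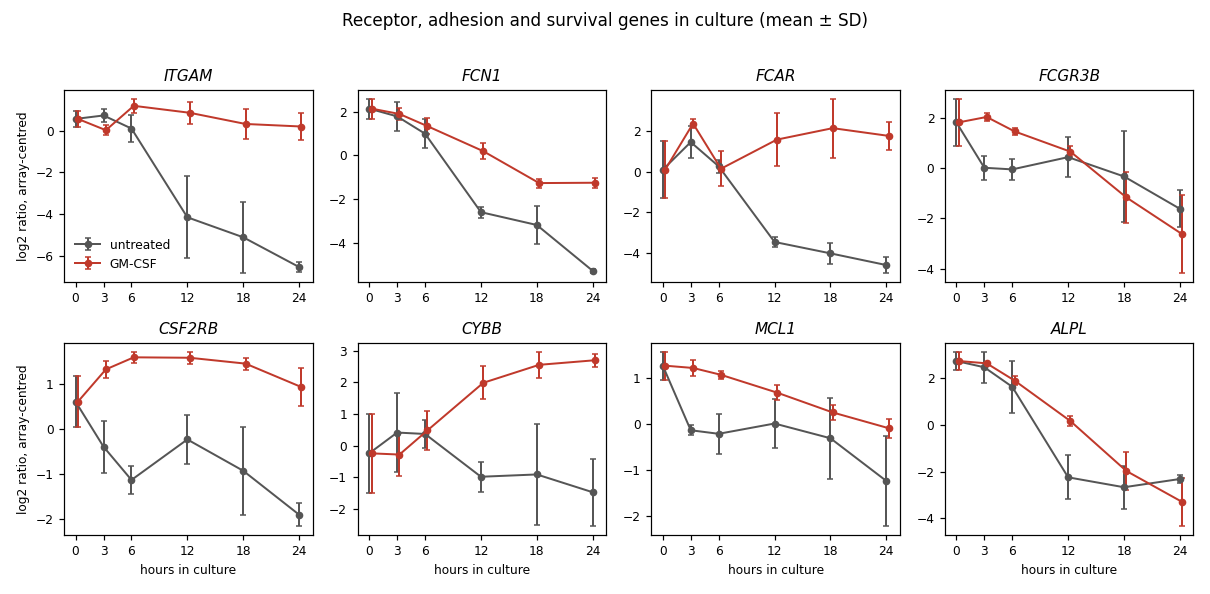
Centred log2 ratios of 8 receptor, adhesion and survival genes against hours in culture, as mean ± SD for untreated cells (grey) and GM-CSF (red), with the 9 time-zero arrays as the shared first point and n = 3 at each later point. ITGAM and FCAR fell in untreated cells from 12 h and stayed near or above time zero with GM-CSF, whereas ALPL was lower at 24 h under both conditions (-5.05 ± 0.42 and -6.04 ± 0.42, SE).

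Of the lists on survival and apoptosis, 2 were called higher over the 5 times. BCL2 family and other survival genes had 8 higher and 3 lower of 14 (adjusted p = 0.0347, and 0.218 with an estimated correlation). BCL2A1 (2.72 ± 0.19), CFLAR, an inhibitor of caspase 8 activation (2.61 ± 0.19), and MCL1 (1.01 ± 0.16) were higher. Caspases had 5 higher and 0 lower of 7 (adjusted p = 0.0295, and 0.218 with an estimated correlation). CASP9 (1.90 ± 0.19), CASP4 (2.01 ± 0.21), CASP5 (1.71 ± 0.43) and CASP8 (1.39 ± 0.21, not called by its most precise probe set) were higher. Over 12, 18 and 24 h alone neither list was called (adjusted p = 0.0613 and 0.18). Pro-apoptotic BCL2 relatives had 7 higher and 2 lower of 12 (adjusted p = 0.0578). Those higher included BCL2L11, which encodes BIM (3.17 ± 0.22), CYCS, cytochrome c (1.28 ± 0.15), and BAX (0.97 ± 0.12, but -0.10 by its most precise probe set). Death receptors and ligands had 7 higher and 7 lower of 19 (median -0.01, test upward, adjusted p = 0.668), with FAS (1.95 ± 0.27) and TNFRSF1A (1.44 ± 0.18) higher. The p53 targets had 7 higher and 6 lower of 14 (adjusted p = 0.28), with CDKN1A, a cell-cycle inhibitor, higher (2.72 ± 0.21).

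Lists of protein synthesis, protein turnover and energy metabolism were among those called higher, and none of these calls held with an estimated correlation. Cytosolic ribosomal proteins had 37 higher and 0 lower of 42 (adjusted p = 4.05e-07, and 0.386 with an estimated correlation), with RPL8 (1.38 ± 0.13) and RPL6 (1.42 ± 0.17). Translation factors had 28 and 2 of 34 (adjusted p = 6.21e-07), with EIF2S1 (1.71 ± 0.13) and EIF3I (1.76 ± 0.13). Proteasome subunits had 26 and 2 of 33, or 27 and 2 adjusted over the list alone (adjusted p = 6.06e-07), with PSMA2 (2.42 ± 0.15) and PSMC4 (1.65 ± 0.12). Chaperones had 22 and 3 of 31 (adjusted p = 7.32e-06), with XBP1 (2.34 ± 0.12), HSP90AA1 (2.23 ± 0.13) and DNAJB9 (3.67 ± 0.24). Oxidative phosphorylation had 32 and 4 of 45 (adjusted p = 7.32e-06, and 0.286 with an estimated correlation), with CYC1 (1.24 ± 0.10) and SDHD (2.02 ± 0.18) beside NDUFV2. Glycolysis and hypoxia-inducible genes had 15 and 7 of 29 (adjusted p = 0.0162), with ENO1 (2.62 ± 0.16), PGK1 (2.20 ± 0.19) and ADM (2.50 ± 0.14). Antioxidant and NRF2 target genes had 16 and 0 of 22 (adjusted p = 1.87e-05), with TXN (2.24 ± 0.14), GCLM (2.85 ± 0.24) and NFE2L2 (2.84 ± 0.25). Lysosome and autophagy genes had 24 and 3 of 34 (adjusted p = 0.00018, and 0.286 with an estimated correlation), with GLA (2.11 ± 0.19) and ATP6V1B2 (1.47 ± 0.16). Actin cytoskeleton and motility genes had 28 and 1 of 35 (adjusted p = 6.06e-07, and 0.286 with an estimated correlation), with RHOA (2.50 ± 0.20), ARPC3 (1.78 ± 0.16) and CFL1 (1.67 ± 0.15). MHC class I and antigen processing had 9 and 1 of 15 (adjusted p = 0.0158, and 0.408 with an estimated correlation), with PDIA3 (1.54 ± 0.17). The other lists of this group had adjusted p = 0.218 with an estimated correlation. MHC class I was not called over 12, 18 and 24 h alone (adjusted p = 0.113). All these lists were compared with untreated cells of the same times, in which spike-in signals and the actin 3′ minus 5′ difference were higher at 24 h than at time zero.

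The 2 lists called lower with GM-CSF over the 5 times were interferon-induced genes and platelet markers. Interferon-induced genes had 4 higher and 17 lower of 29 (adjusted p = 0.0347, and 0.601 with an estimated correlation), and 1 higher and 20 lower over 12, 18 and 24 h (adjusted p = 0.00782, and 0.55 with an estimated correlation). The antiviral genes MX2 (-1.42 ± 0.16) and EIF2AK2 (-1.10 ± 0.16) were among them. Platelet markers had 0 higher and 8 lower of 8 (adjusted p = 0.0115, and 0.218 with an estimated correlation), with CLU (-1.79 ± 0.20) and SELP (-2.18 ± 0.30). They were higher in untreated cells at 3 h (6 higher and 0 lower) and at 6 h (5 and 0), the arrays that stood apart. The list was not called over 12, 18 and 24 h alone (adjusted p = 0.13). Immediate-early genes had 14 higher and 5 lower of 25 (adjusted p = 0.0527, and 0.0121 over 12, 18 and 24 h, where it was 0.248 with an estimated correlation), with EGR3 (3.11 ± 0.21) and MAFF (3.11 ± 0.26) higher. MHC class II and antigen presentation had 6 and 3 of 15 (adjusted p = 0.289, and 0.0395 over 12, 18 and 24 h, where it was 0.369 with an estimated correlation), with HLA-DRA (2.34 ± 0.20) and CD74 (1.29 ± 0.18). Cholesterol synthesis was not called (6 and 3 of 15, adjusted p = 0.415), with IDI1 higher (3.09 ± 0.16) and DHCR7 lower (-1.28 ± 0.13). Granule proteins were not called (6 and 7 of 22, adjusted p = 0.993), with MMP9 higher (1.81 ± 0.20) and CHI3L1 lower (-1.39 ± 0.26), and neither were cell cycle genes (7 and 14 of 27, adjusted p = 0.373). Among cell-type markers, those of neutrophils had 6 higher and 4 lower of 15 (median -0.16, test upward, adjusted p = 0.838). S100A8 was higher (2.10 ± 0.18) and FCGR3B was not called (0.38 ± 0.32, and -0.11 after quantile normalization). Markers of eosinophils (0 and 3 of 6, adjusted p = 0.119), monocytes (2 and 3 of 10, adjusted p = 0.48) and T and NK cells (2 and 3 of 19, 2 lower adjusted over the list alone, adjusted p = 0.838) were not called. Those of B cells (0 and 4 of 6, adjusted p = 0.246) and erythroid cells (1 and 4 of 5, median -0.63, mean 0.09, adjusted p = 0.42) were not called either.

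**Figure D4:**
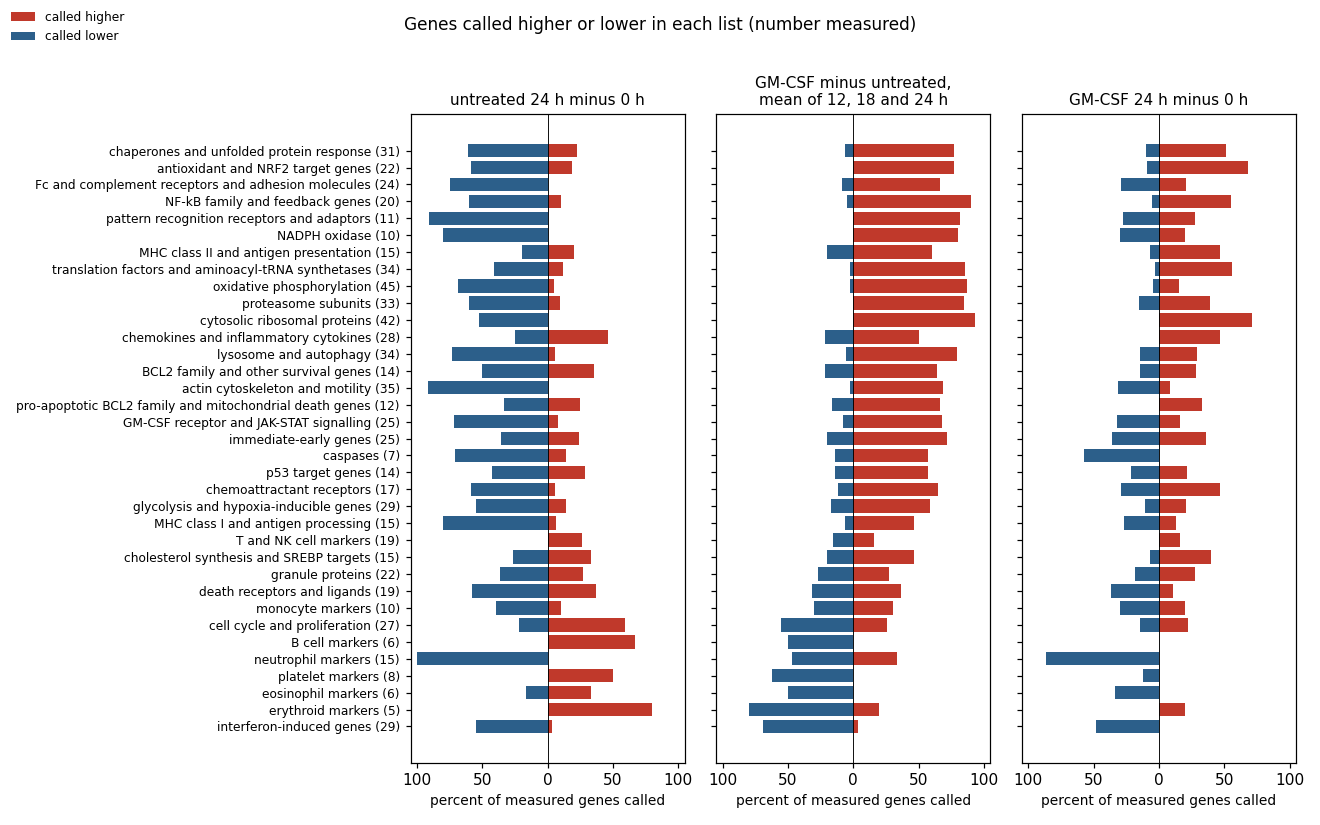
Percent of the measured genes of each of 35 lists called higher (red, to the right) or lower (blue, to the left) in untreated cells at 24 h against time zero, in GM-CSF-treated against untreated cells over 12, 18 and 24 h, and in GM-CSF-treated cells at 24 h against time zero; the number measured stands after each name. Neutrophil markers were lower in the first and last panel (15 and 13 of 15), and ribosomal proteins were higher with GM-CSF in the middle and last panel (39 and 30 of 42).

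The GM-CSF effect differed between times for 2399 of 6275 genes (moderated F test). The largest F values belonged to OAZ1 (98.4), TMSB4X (85.4), FTL (63.5), PRSS22 (60.2), PRDX1 (56.3), B2M (45.5), TAGLN2 (40.4) and DENND2B (40.0). PRDX1, a peroxidase of the antioxidant system, went from -2.37 ± 0.42 at 3 h to 5.32 ± 0.42 at 24 h, rising over time in treated cells (4.37 ± 0.34 above time zero at 24 h). HMOX1 likewise went from -5.24 ± 0.89 to 6.46 ± 0.89. The 3 h differences of both genes are against the untreated arrays that stood apart. On the untreated 3 h and 6 h arrays OAZ1, TMSB4X, FTL, B2M and DENND2B had fallen probe sets and TAGLN2 was low. Over 12, 18 and 24 h alone none of these 6 genes nor PRSS22 was called, PRDX1 kept its call, and 82 genes were called in all.

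Against time zero, cells kept 24 h with GM-CSF had higher transcripts of chemokines and inflammatory cytokines and lower transcripts of neutrophil markers. The largest rises were in F3, tissue factor (6.19 ± 0.97), the chemokine CCL3 (5.79 ± 0.77), CCRL2 (5.79 ± 0.42), CYP1B1 (5.58 ± 0.61) and the chemokine CCL4 (5.54 ± 0.49). The largest falls were in ALPL (-6.04 ± 0.42), the folate receptor FOLR3 (-5.73 ± 0.89), APOBEC3B (-5.06 ± 1.16), the endopeptidase MME (-4.90 ± 0.41) and TPST1 (-4.77 ± 0.60). APOBEC3B was not called in the setting first planned. IL1RN (2.43 ± 0.30), CXCL8 (3.11 ± 0.37) and IL1B (2.18 ± 0.41) were above time zero with GM-CSF and below it without (-3.71 ± 0.30, -1.33 ± 0.37 and -1.54 ± 0.41). The fall of CXCL8 was not called after quantile normalization or as deposited, and that of IL1B not in the setting first planned. CSF2RA (0.04 ± 0.38), CFLAR (0.35 ± 0.34) and ITGAM (-0.36 ± 0.52) were not called against time zero with GM-CSF, whereas CXCR1 (-4.05 ± 0.27), CXCR2 (-2.82 ± 0.27), FCGR3B (-4.45 ± 0.58) and MCL1 (-1.37 ± 0.30) were lower. In all 1913 genes differed at 24 h, 953 higher and 960 lower (1223 and 778 as deposited), and 1616, 1408, 1722 and 1786 at 3, 6, 12 and 18 h. Their splits were 714 higher and 902 lower (613 and 1142 as deposited), 723 and 685 (602 and 991), 935 and 787 (811 and 988), and 917 and 869 (989 and 827).

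Of the 35 lists 14 were called after 24 h with GM-CSF, on arrays whose spike-ins lay at 0.75 (-0.88 at time zero) and whose actin 3′ minus 5′ difference lay at -0.19 (-0.64 at time zero). Chemokines and inflammatory cytokines were higher (13 genes higher and 0 lower of 28, adjusted p = 2.3e-06) and neutrophil markers lower (0 and 13 of 15, median -3.40, adjusted p = 6.08e-15). These were the 2 calls kept with an estimated correlation (adjusted p = 0.0119 and 0.0316). Examples were CCL2 (5.42 ± 0.33) and CXCL2 (4.79 ± 0.44) of the first and TNFRSF10C, a decoy death receptor (-2.83 ± 0.18), and VNN2 (-4.07 ± 0.32) of the second. Also higher were ribosomal proteins (30 and 0 of 42, 33 higher adjusted over the list alone, adjusted p = 5.8e-10, and 0.447 with an estimated correlation) and translation factors (19 and 1 of 34, 2 lower adjusted over the list alone, adjusted p = 3.59e-07, and 0.145). NF-kB genes (11 and 1 of 20, adjusted p = 0.00011, and 0.355), NRF2 targets (15 and 2 of 22, 17 higher adjusted over the list alone, adjusted p = 0.00011, and 0.215) and chaperones (16 and 3 of 31, 17 and 4 adjusted over the list alone, adjusted p = 0.00119, and 0.279) were higher too. MHC class II (7 and 1 of 15, 8 higher adjusted over the list alone, adjusted p = 0.0115, and 0.363) and proteasome subunits (13 and 5 of 33, 15 higher adjusted over the list alone, adjusted p = 0.034, and 0.729) were called higher, as were cholesterol synthesis (6 and 1 of 15, 7 higher adjusted over the list alone, adjusted p = 0.034, and 0.145), pro-apoptotic BCL2 relatives (4 and 0 of 12, adjusted p = 0.0426, and 0.223) and T and NK cell markers (3 and 0 of 19, 0 adjusted over the list alone, adjusted p = 0.0424, and 0.776). Caspases (0 and 4 of 7, adjusted p = 0.0314, and 0.215) and interferon-induced genes (0 and 14 of 29, adjusted p = 1.12e-06, and 0.447) were lower. CD83 (4.61 ± 0.40), HLA-DRA (3.26 ± 0.36), CYCS (3.19 ± 0.27), CASP1 (-3.19 ± 0.53) and MX2 (-2.59 ± 0.29) were among their members. The JAK-STAT list (4 and 8 of 25, 9 lower adjusted over the list alone, median 0.05, test downward, adjusted p = 0.434) and pattern recognition receptors (3 and 3 of 11, median 0.15, test downward, adjusted p = 0.679) were not called.

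The changes with and without GM-CSF were compared across genes, which are not independent replicates. With the time-zero arrays split between both comparisons, Pearson's r was 0.353, 0.193, -0.013, 0.161 and 0.249 at 3, 6, 12, 18 and 24 h, and with the split turned round 0.343, 0.227, 0.102, 0.267 and 0.355. With shared time-zero arrays r was 0.396, 0.255, 0.077, 0.246 and 0.324, where unchanged groups simulated against the same arrays gave 0.249. The covariance was 0.36, 0.207, 0.066, 0.264 and 0.563, against a simulated 0.041. Genes lower under both conditions numbered 295, 165, 215, 435 and 738, where independent lists would give 115.7, 71.6, 115.9, 200.5 and 348.8. Genes higher under both numbered 251, 182, 97, 158 and 312, where independent lists would give 72.1, 58.8, 108, 175.9 and 356. At 24 h the direction turned after quantile normalization, with 320 genes higher under both where independent lists would give 275.2. The expected numbers leave out the shared time-zero arrays, so an excess of genes over them is not by itself a shared effect. The simulated covariance is the part that these shared arrays add. With the time-zero arrays split, the covariance was 0.332, 0.166, -0.013, 0.186 and 0.461. At 3, 6, 18 and 24 h the shared arrays therefore do not account for all of it. Whether the rest came from the cells or from the arrays was not tested. Opposite calls were made for 74, 82, 216, 188 and 311 genes, which at 24 h included IL1RN, IL1B and CXCL8.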

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

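In this part the tests of the fall of abundant transcripts and of RNA degradation were chosen after the results were seen, as were the comparisons with all dim genes and with dim probe sets left out by the filter. The spike-in test of the rise of dim probe sets was written before its result was seen, and the splits of the arrays were planned.

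Among the 9 time-zero arrays, 1 array lay far from the others for 11 of 93 values tested, 9 of them genes, where chance would give about 1 in 20. The gap to the nearest array, as a share of the whole range, was 0.625 for SOCS1, 0.61 for PPARG, 0.782 for LHFPL2, 0.535 for SERPINB1, 0.51 for RARA, 0.499 for FRAT2, 0.63 for CYP1B1, 0.681 for CSF2RB and 0.562 for FAS. It was 0.861 for the actin 3′ minus 5′ difference and 0.716 for that of GAPDH. Replicate 5 was the array apart in 7 of the 11, lowest in SERPINB1, RARA, FRAT2, CSF2RB and FAS and highest in both 3′ minus 5′ differences. No explanation of this was tested.

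The GM-CSF effect differed between times by the interaction test for 2399 genes. Among the named genes F was 98.38 for OAZ1, 85.35 for TMSB4X, 63.49 for FTL, 60.22 for PRSS22, 56.26 for PRDX1, 45.52 for B2M, 40.35 for TAGLN2 and 39.99 for DENND2B. It was 30.95 for HMOX1, 23.37 for CCRL2, 22.62 for DUSP2, 9.194 for MME and 5.305 for NACC2, all of which were named for other reasons and had effects of opposite sign at different times. PRDX1 and HMOX1, both induced by oxidative stress, went from lower to higher with GM-CSF between 3 and 24 h. The 3 h and 6 h effects of all these genes are against the untreated arrays that stood apart.

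The fall of OAZ1, TMSB4X, FTL and 1 probe set of B2M was confined to the 6 untreated arrays of 3 and 6 h. If transcripts had been lost in the cells, all probe sets of a gene would fall together. In the 6 genes with a fallen and another probe set, the most and least fallen differed by a median of 5.258 on the log2 scale. A gap was partly built in, since genes entered only with a probe set that had not fallen as far. That probe set changed little from time zero in CXCL8 (0.623), TNFRSF1B (0.512), GAPDH (-0.303), SFI1 (0.164) and DENND2B (0.004). For these genes that argues against loss in the cells. B2M is less clear (-1.473), since all 3 of its probe sets were below every other array. The 3′ probe set of the brightest bacterial spike-in, CreX, lay lower relative to BioB, BioC and BioDn on these 6 arrays than on the other 33. The difference was -1.782 on the log2 scale, and 1 of the 33 was as low. That array, untreated 24 h replicate 2, lay at -1.878, below the lowest of the 6 (-1.85), without the fall of the 13 probe sets. A low CreX 3′ signal therefore does not by itself mark that fall. The CreX 5′ probe set differed less. It lay at -0.666 and -0.616 at 3 and 6 h, where BioB, BioC and BioDn lay at -0.09 and 0.091. At time zero it lay at -0.662, where they lay at -0.875. The human Alu control probe set lay at the floor (-6.644 on the log2 scale) on all 6 arrays, while its lowest value on the other 33 was -1.333. The actin control probe sets fell unequally. At 3 and 6 h the 3′ set lay at -3.78 and -4.03 (-0.30 at time zero) and the 5′ set at -2.04 and -1.56 (0.34 at time zero). A scanning or saturation difference of these arrays remains a possible explanation. A biological change at 3 and 6 h in genes with 1 kept probe set, among them OAZ1, TMSB4X and FTL, was not tested.

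Spike-in signals outside the comparisons lay above their time-zero level, at a deposited log2 ratio of 0.797 in untreated cells at 18 h, 1.393 in untreated cells at 24 h and 0.748 with GM-CSF at 24 h. Against time zero, the dim genes called higher in untreated cells at 24 h, such as CLGN, FRK and RAG1, rose by a median of 1.67, and the spike-ins on the same centred scale rose by 1.67 ± 0.33 (SE). The difference was 0.002, but these genes were chosen because they rose, and the median of all dim genes, called or not, lay at 1.15 and that of dim probe sets left out by the filter at 0.93. These 2 medians are not free of selection either. The filter could keep a dim probe set through the untreated 24 h arrays alone, and it left out those that stayed low on them. They therefore cannot decide the question. Rescaling of arrays with less labelled RNA from the cells is therefore left open, and 103 of the 1330 genes rose by over 1 more than the spike-ins. RNA degradation could not be decided: the actin 3′ minus 5′ difference rose by 1.42, but that of GAPDH by 0.158, or by 0.34 without time zero replicate 5, which stood apart in this measure. A gain of these transcripts in the cells relative to the rest stays open and was not tested.

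Other splits of the same arrays were fitted in the same way. For GM-CSF minus untreated at 3, 6, 12, 18 and 24 h the 10 splits are too few for a share under 0.05, with 1 split in each as large as the real one (itself): 1415 genes against 2 in the highest other, 1492 against 1, 2589 against 2, 2615 against 2 and 3850 against 2. For the mean over times none of the other 99 splits drawn called as many (4438 genes, highest other 1914). For the interaction (2399), 2 of 100 splits gave as many and 1 gave 2695, more than the real one. These splits exchanged labels within each time, which removes the GM-CSF effect itself. They therefore cannot decide whether a difference of that effect between times is due to chance. For untreated cells against time zero, none of the other 99 splits drawn called as many at any time. The real number against the highest other was 1439 against 383 at 3 h, 1166 against 309 at 6 h and 1649 against 1237 at 12 h. It was 2652 against 2341 at 18 h and 4624 against 2915 at 24 h. Without untreated replicate 2 of the same time, the real number was 396 at 12 h and 726 at 18 h. With GM-CSF none of 99 did so either, at 3 h (1616 against 450), 6 h (1408 against 176), 12 h (1722 against 883), 18 h (1786 against 553) and 24 h (1913 against 605). Not all possible splits were drawn for the mean over times or against time zero. The labels do not show that the arrays of a group are independent, so splits of arrays cannot exclude chance between donors or cultures. For the mean GM-CSF effect no other split called as many as 21 gene lists, although 1 gave 19 and the median of the other splits was 10. This bears on the number of lists only. Chance cannot be excluded for any single list in this way. For the 13 gene lists in untreated cells at 24 h it cannot, since 34 of 100 splits gave as many, 1 gave 21 and the median of the other splits was 11.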

How the results depend on the processing

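The alternatives as first written (the setting planned for intensities, tried on ratios once their unit was known), bright probe sets only, most precise probe set, as deposited, 12, 18 and 24 h only, and time zero replicates 4 to 9 only were chosen after seeing the data; the others were planned. Of 398 differences of 275 named genes, 383 kept sign and call after quantile normalization (13 lost the call, 1 gained it and 1 changed sign), 393 with an offset of 1, 384 with no filter, 388 as deposited and 366 as first written (27 lost it and 4 changed sign). Of 7638 differences with 1 array left out, 7594 kept them. Causes were not tested, except where fewer genes or arrays entered the test. The number of arrays limits precision.

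Signs turned for FCGR3B over the mean (quantile normalization -0.108, 12, 18 and 24 h only -0.542), IFITM3 over the mean (12, 18 and 24 h only -0.481), CD22 over the mean (no filter 0.2) and CD79A over the mean (as first written 0.212). In untreated cells at 24 h they turned as first written for MYO5A (0.321), BCL6 (0.254) and ITGA2B (-0.188), and for CXCR4 with no filter (-0.256) or time zero replicates 4 to 9 (-0.026). With the most precise probe set they turned for BAX (-0.098 over the mean, 1.17 in untreated cells at 24 h), CXCR2 (1.566) and RELA (0.186).

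Gene lists called in untreated cells at 24 h (13) numbered 21 with no filter, 20 as first written, 8 with bright probe sets only, 0 with estimated correlation and 26 by fry, and those of the mean GM-CSF effect (21) numbered 0 with estimated correlation. Bright probe sets alone gave 2998 genes in untreated cells at 24 h, the compared arrays alone gave 1193 for GM-CSF minus untreated at 18 h, and 12, 18 and 24 h only gave 82 for the interaction. At least 2-fold were 1949 genes of the mean effect, and 993 and 1722 in untreated cells at 12 and 18 h. Quantile normalization, the planned scaling, gave 2616 genes for GM-CSF minus untreated at 24 h, sharing 2554 of the 3850 main calls. In untreated cells at 24 h it gave 3572, sharing 3524 of the 4624 main calls. The similarity r was 0.401, 0.244, 0.023 and 0.351 at 3, 6, 12 and 24 h after quantile normalization, and 0.227, 0.102, 0.267 and 0.355 at 6, 12, 18 and 24 h with the split turned round.

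With 1 array left out, untreated cells gave 946 (without untreated 3 h replicate 1) to 1542 genes at 3 h, 736 (without untreated 6 h replicate 1) to 1310 at 6 h, 396 (without untreated 12 h replicate 2) to 1956 at 12 h, and 726 (without untreated 18 h replicate 2) to 2927 at 18 h. GM-CSF minus untreated gave 1630 (without untreated 12 h replicate 2) to 2510 at 12 h and 1536 (without untreated 18 h replicate 2) to 2643 at 18 h. CXCR4 in untreated cells at 24 h ranged from -0.158 to 0.539, and r from 0.304 to 0.394 at 3 h, 0.134 to 0.242 at 6 h, -0.065 to 0.037 at 12 h, 0.103 to 0.206 at 18 h and 0.19 to 0.28 at 24 h.

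Replicate numbers did not pair untreated with GM-CSF arrays of the same time: of 15 pairs none correlated above 0.1. A block moved no count of calls by over 1.5 times, but it changed which genes were called against time zero. With a replicate block, untreated cells kept 1029 of 1439 main calls at 3 h, 766 of 1166 at 6 h and 950 of 1649 at 12 h. The mean GM-CSF effect kept 4405 of 4438. Across times, untreated replicate 2 had the highest median of kept probe sets before centring. Its log2 medians were -0.012, 0.087, 0.324, 0.48 and 0.597 at 3, 6, 12, 18 and 24 h. With GM-CSF, replicate 2 was highest at 18 h only (-0.032). Whether the untreated arrays of replicate 2 shared a source across times was not tested. The planned filter at the 75th percentile of signal could not be resolved from the recovered constants and was not run, the planned mean of probe sets became the main choice, and the block by time was not run for the gene lists of untreated cells at 24 h.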

Other observations

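In this part the tests on monocyte and neutrophil markers were chosen after the results were seen.

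After 3 h of culture with GM-CSF, single genes of cytokine signalling and stress were above time zero (3 arrays against 9). IL3RA was higher by 3.08 ± 0.40 (SE) and SOCS2, a feedback inhibitor of STAT signalling, by 3.07 ± 0.50, reaching 4.03 ± 0.50 at 12 h. GADD45A, a stress-response gene, rose by 4.96 ± 0.42. On the untreated 3 h arrays, which stand apart from the other groups by their CreX signal and collapsed probe sets, CXCL2 (3.76 ± 0.44), CCL4 (3.65 ± 0.49), CD83 (3.68 ± 0.40), NFKBIE (3.59 ± 0.41), NR4A3 (3.42 ± 0.28) and EGR3 (3.40 ± 0.39) were higher. On these arrays 13 chemokine and cytokine genes were called higher and 2 lower of 28 (14 higher adjusted over the list alone, adjusted p = 0.00048, and 0.113 with an estimated correlation). Of 20 NF-kB genes 10 were higher and 0 lower (11 and 1 adjusted over the list alone, adjusted p = 7.78e-05, and 0.406 with an estimated correlation).

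Interferon-induced genes were compared with time zero at each time of culture with GM-CSF. Of 29 genes 2 were higher and 9 lower at 6 h (12 lower adjusted over the list alone), 0 and 23 at 12 h (median -1.84), 0 and 25 at 18 h (median -1.91, 27 lower adjusted over the list alone) and 0 and 14 at 24 h (median -1.52). At 12 h IFIT1, which binds viral RNA, lay at -4.23 ± 0.65, IFIT3 at -3.33 ± 0.60 and the antiviral gene MX2 at -3.02 ± 0.29. With an estimated correlation the list was called at none of these times (adjusted p = 0.754, 0.311, 0.265 and 0.447). Of the ribosomal protein genes 4, 5, 14, 23 and 30 of 42 were called higher at 3, 6, 12, 18 and 24 h (3, 1, 20, 26 and 33 adjusted over the list alone) and none lower. With an estimated correlation that list had adjusted p = 0.898, 0.782, 0.555, 0.477 and 0.447.

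After 24 h with GM-CSF 2 genes abundant in macrophages, the mannose receptor MRC1 (4.54 ± 0.67) and the protease CTSL (4.38 ± 0.69), were higher than at time zero. A larger share of monocytes with their time-zero profile would raise all their markers, but of 10 measured 3 were called lower (FGL2, CD1D and CPVL), which argues against it. The 2 called higher were MRC1 and CTSL themselves, whose rise prompted the test. Monocytes that change in culture could not be told apart from a change of the neutrophils: neutrophil markers fell by a median of -3.395 with GM-CSF, and by -2.76 without it, so their fall does not decide. Whether neutrophils themselves took up these genes was not tested.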
